A study of Mus musculus with 8 samples.

How the data were processed

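Livers of 4 wild-type and 4 eIF2α heterozygous mice were analysed from 2 deposited tables. Per the labels' protocols, livers were snap-frozen, RNA was extracted with Trizol and treated with DNaseI, and ribosomal RNA was removed with a Ribo-Zero kit before Illumina library preparation. The genome build was mm10, and fastp 0.19.5, Bowtie2 2.2.9, GATK 3.8 and SAMtools 1.9 were used, per the submitters' processing notes, which give no role for each tool. The program that counted reads, its annotation release and whether it used strand are not given in the sources used here. The count table deposited by the authors holds estimated counts per gene, not normalized, for 56077 genes and loci in 8 columns, and 90.0% of its values are exactly whole. The other values carry fractions, so reads were split between features, and for genes with close copies the count depends on that split. Library totals were 27799097 (W32), 27030799 (W33), 25975780 (W76), 25626355 (W90), 24496149 (H11), 28564357 (H12), 22177979 (H15) and 22232757 (H75). The deposited table also holds 541 unannotated loci, with 0.431 to 0.977% of the counts of a library.

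Column names give the group by their first letter, W or H, and the table is named for wild type against heterozygotes. They carry no replicate number, so each column was used as 1 replicate of its group with no pairing. In the authors' deposited table of comparisons, fold (a ratio), log2 fold change, p-value and adjusted p-value are given for each gene, per the file headers, with the gene length in bases. Its table name points to DESeq2. Its header does not give a direction, and 99.5% of its log2 fold changes over 13971 shared genes had the sign of heterozygous over wild type. It marks 74 genes as significant, 52 higher and 22 lower, and the smallest absolute log2 fold change among them is 1.001.

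Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 14261, scaled with TMM factors (0.900 to 1.06) and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with group as the only term. Calls had a Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM-scaled library sizes, and a standard error of a log2 fold change is its size divided by the square root of the F statistic. The version of the quasi-likelihood method had not been fixed beforehand. The default of edgeR was used, and the newer method, added as an alternative, called 1 gene. Results of both were known when the default was kept. Eif2s1 was also tested with an exact two-sided permutation test of log2 CPM, and measures of library structure with exact two-sided permutation tests with Benjamini-Hochberg adjustment over 22 measures.

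Gene lists were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. Of 47 lists, 44 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, from limma 3.58.1. A list's members were also adjusted over the list alone. Named genes are Eif2s1, Eif2a, Eif2s2, Eif2s3x and the 4 eIF2α kinases, up to 4 members of lowest p in each described list, and genes past the threshold. As no gene passed, the rule named the 10 of lowest p in each direction with a mean of at least 1 CPM, a symbol that is not a predicted gene model and full separation of the groups. Other genes are named as chosen after their values were seen.

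Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, an adjusted p under 0.1, a test against a fold of 1.2, removal of abundant, mitochondrial and ribosomal RNA genes, and leaving out each library in turn. Added after seeing the data were a robust fit, the newer quasi-likelihood method, removal of unannotated loci, DESeq2, limma-voom and estimated-correlation fits without library H15, removal of a gene length trend, and tests of annotation terms on the DESeq2 calls and with camera. Over-representation of terms of 10 to 500 genes used a one-sided hypergeometric test against the tested genes with an annotation.

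Within each group every pair of libraries differed by more than sampling noise (chi-square per gene 22.1 to 180), so none was a duplicate. On simulated data with 50 genes changed at each of 4 folds, edgeR recovered 18% at a fold of 1.5, 64% at 2, 94% at 4 and 98% at 8, with 11 false calls among 148. DESeq2 recovered 36, 74, 94 and 98% with 48 false calls among 199, and limma-voom 16, 64, 92 and 98% with 10 among 145. Of 40 simulated lists with no change, camera called 0 with either correlation and fry 2. The simulated genes varied independently of each other, so these counts do not cover lists whose genes move together. In the data the estimated correlation reached 0.886, in the list of cytosolic ribosomal proteins. Coordinates come from GENCODE mouse release 21 on GRCm38, the assembly that mm10 denotes, in which 13966 of 13972 tested Ensembl identifiers were found. Analyses also used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.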

Results

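Livers of 6-month-old C57BL/6 mice were compared between wild-type animals and animals heterozygous for eIF2α, the subunit of translation initiation factor 2 whose phosphorylation slows protein synthesis under stress. Total RNA depleted of ribosomal RNA was sequenced from 4 wild-type and 4 heterozygous livers of fed mice. The labels write the heterozygous genotype as flox/+ and name no recombinase, and their growth protocol calls the mice of both groups wild-type. The deposited count table held 25626355 to 27799097 counts per wild-type library and 22177979 to 28564357 per heterozygous library. Wild-type libraries are called W32, W33, W76 and W90, and heterozygous libraries H11, H12, H15 and H75, after the columns of that table. No label says that the mice came from separate litters. P-values set the group difference against the spread within groups and treat the samples as independent, which shared litters would break. The single comparison asks how the liver transcriptome of heterozygous mice differs from that of wild-type mice.

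Eif2s1, the gene that encodes eIF2α, was lower in all 4 heterozygous libraries than in any wild-type library. Its expression averaged 30.0 CPM in wild-type and 22.2 CPM in heterozygous livers (n = 4 each), so the heterozygous mean was 73.8% of the wild-type mean. The wild-type libraries W32, W33, W76 and W90 had 28.4, 28.8, 32.8 and 30.1 CPM. The heterozygous libraries H11, H12, H15 and H75 had 20.5, 22.3, 20.8 and 25.1 CPM. These values rest on 489 to 852 reads per library. The log2 fold change was -0.44 (SE 0.095), and an exact two-sided permutation test over 70 assignments gave p = 0.0286, the smallest p it can give. Over all genes Eif2s1 did not pass edgeR's quasi-likelihood test (adjusted p = 0.315). DESeq2 gave an adjusted p of 0.0207, and over 18 alternative settings the adjusted p ran from 0.0207 to 0.633. Eif2s1 (ENSMUSG00000021116) is a protein-coding gene on the plus strand of chromosome 12, from 78861819 to 78887010 of GRCm38. Reads per gene do not separate the 2 alleles.

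The other subunits of the factor differed little between the genotypes. Eif2s2, the β subunit, had a log2 fold change of 0.08 (SE 0.12) and Eif2s3x, the γ subunit, of 0.04 (SE 0.081). Eif2a, a separate initiation factor whose symbol the genotype label prints, averaged 26.1 ± 0.949 CPM in wild-type and 26.3 ± 2.23 CPM in heterozygous livers (SD, n = 4 each). With library totals alone as the scaling, which moved the median log2 fold change of all genes by -0.086, Eif2s2, Eif2s3x and Eif2a had negative values of -0.018, -0.048 and -0.078. Eif2a was also negative with upper quartile scaling (-0.0034), without W32 (-0.013) and without H75 (-0.047). Of 15 eIF2, eIF2B and related initiation factor genes, Eif2s1 was the 1 that passed adjusted over the list alone (adjusted p = 0.0148, edgeR).

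Among the kinases that phosphorylate eIF2α, Eif2ak1 was higher in all 4 heterozygous libraries (log2 fold change 0.18, SE 0.081) without passing over all genes (adjusted p = 0.544, edgeR). Eif2ak2 had a log2 fold change of -0.30, Eif2ak3 of 0.14 and Eif2ak4 of -0.36. Eif2ak4 was at 10.2 CPM in H15 and 6.01 to 6.15 CPM in the other heterozygous libraries, and without H15 it passed edgeR's test (log2 fold change -0.58, adjusted p = 0.0398, range over 18 settings 0.0398 to 0.934). Eif2ak3 turned negative without H12 (-0.094) or without H75 (-0.031). Ppp1r15a, an inducible subunit of the phosphatase that acts on eIF2α, was higher in all 4 heterozygous libraries (log2 fold change 0.66, SE 0.16). It was the 1 of 10 kinase and phosphatase genes that passed adjusted over the list alone (adjusted p = 0.0255, edgeR).

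Across the transcriptome, single genes separated the genotypes but none passed an adjusted p of 0.05 among 14261 genes with edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 1332 genes, 699 higher and 633 lower in heterozygous livers, where chance gives 713 on average. Such counts vary widely when genes move together. Of the 35 splits of the 8 libraries into 4 and 4, 8 gave as many, the real one included, so chance was not excluded. DESeq2 called 152 genes, 91 higher and 61 lower, and limma-voom called 0. In 294 genes all 4 heterozygous libraries lay above all wild-type libraries and in 331 below them. Together these were 4.38% of genes, against 2.86% on average by chance, and the spread of that share was not tested. Without heterozygous library H15 edgeR called 252 genes, 123 higher and 129 lower, and without wild-type library W32 it called 2, 1 in each direction. The authors' deposited table, a DESeq2 comparison of the same groups by its name, held 139 genes with an adjusted p under 0.05, 83 higher and 56 lower. Of these, 138 were among the 152 DESeq2 calls made here. The genes named next are the 10 of lowest p in each direction that averaged at least 1 CPM and separated the libraries fully, and none passed edgeR's test over all genes.

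The lower genes were led by Cidea, a lipid droplet protein that promotes droplet enlargement. Cidea averaged 5.24 ± 1.61 CPM in wild-type and 0.172 ± 0.199 CPM in heterozygous livers (SD, n = 4 each), a log2 fold change of -4.91 (SE 0.53, adjusted p = 0.0546, edgeR). Clstn3, a calsyntenin gene, averaged 34.5 ± 4.42 and 14.1 ± 3.19 CPM, a log2 fold change of -1.30 (SE 0.17, adjusted p = 0.120, edgeR). Cfd, which encodes complement factor D (adipsin), averaged 5.35 ± 3.14 and 0.739 ± 0.123 CPM, a log2 fold change of -2.85 (SE 0.42, adjusted p = 0.136, edgeR). Acaa1b, a peroxisomal thiolase of fatty acid oxidation, averaged 2030 ± 257 and 1310 ± 78.9 CPM. Slc25a10, the mitochondrial dicarboxylate carrier, averaged 212 ± 24.3 and 150 ± 12.8 CPM. The transcriptional corepressor Hr had a log2 fold change of -1.59. The other genes were Samd9l (-0.87), Fam89a (-0.84), Snhg11 (-0.71) and Sh3bgrl2 (-0.58). DESeq2, run on the same libraries that chose these genes, called all 10, with adjusted p from 1.22e-17 for Cidea to 0.00752 for Snhg11. Limma-voom called 0 of them, and on simulated data 48 of 199 DESeq2 calls were false. Over 18 settings the adjusted p of Cidea ran from 1.22e-17 to 0.217 and its log2 fold change from -6.12 to -4.55, the former without H15. In heterozygous libraries Cidea was at 0.0385 to 0.467 CPM, a level of few reads, so the size of this fold change is uncertain. Adipose tissue also expresses Cfd and Cidea, and the adipocyte gene Adipoq reached at most 0.0378 CPM in a wild-type library. Reads of Acaa1b can be shared with its paralog Acaa1a.

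The higher genes included regulators of insulin, growth hormone and amino acid responses. Irs2, an adaptor of the insulin receptor, averaged 27.8 ± 4.53 CPM in wild-type and 62.4 ± 14.4 CPM in heterozygous livers (SD, n = 4 each), 2.25-fold higher (SE of log2 0.17, adjusted p = 0.136, edgeR). Asns, asparagine synthetase, averaged 1.29 ± 0.416 and 15.1 ± 12.0 CPM, 11.7-fold higher (SE of log2 0.57, adjusted p = 0.196, edgeR). In heterozygous libraries Asns ranged from 4.25 CPM in H15 to 32.1 CPM in H75. Igfbp1, a secreted binding protein of insulin-like growth factors whose transcription insulin represses, averaged 69.3 ± 28.5 and 577 ± 427 CPM (adjusted p = 0.196, edgeR). Socs2, a feedback inhibitor of growth hormone signalling, was 3.53-fold higher. Slc38a2, a neutral amino acid transporter, was 1.62-fold higher. Cyp2c70, a bile acid hydroxylase, averaged 426 ± 15.1 and 742 ± 134 CPM. Plk3 was 2.63-fold and Wsb1 2.22-fold higher. The metallothionein Mt2 (47.7-fold) and the transcription factor Egr1 (14.3-fold) had wide ranges, from 6.58 to 348 CPM and from 36.2 to 374 CPM in heterozygous libraries. DESeq2, again on the libraries that chose these genes, called all 10, with adjusted p from 5.25e-07 for Irs2 to 0.00101 for Slc38a2. Limma-voom called 0 of them. Over 18 settings the adjusted p of Irs2 ran from 5.25e-07 to 0.588. The log2 fold changes of Asns, Igfbp1, Mt2 and Egr1, 3.55, 3.06, 5.58 and 3.83 with all libraries, ran from 2.87 to 3.86, from 2.45 to 3.34, from 4.67 to 6.14 and from 2.61 to 4.15, lowest without H75 for Asns and without H12 for the others.

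**Figure D1:**
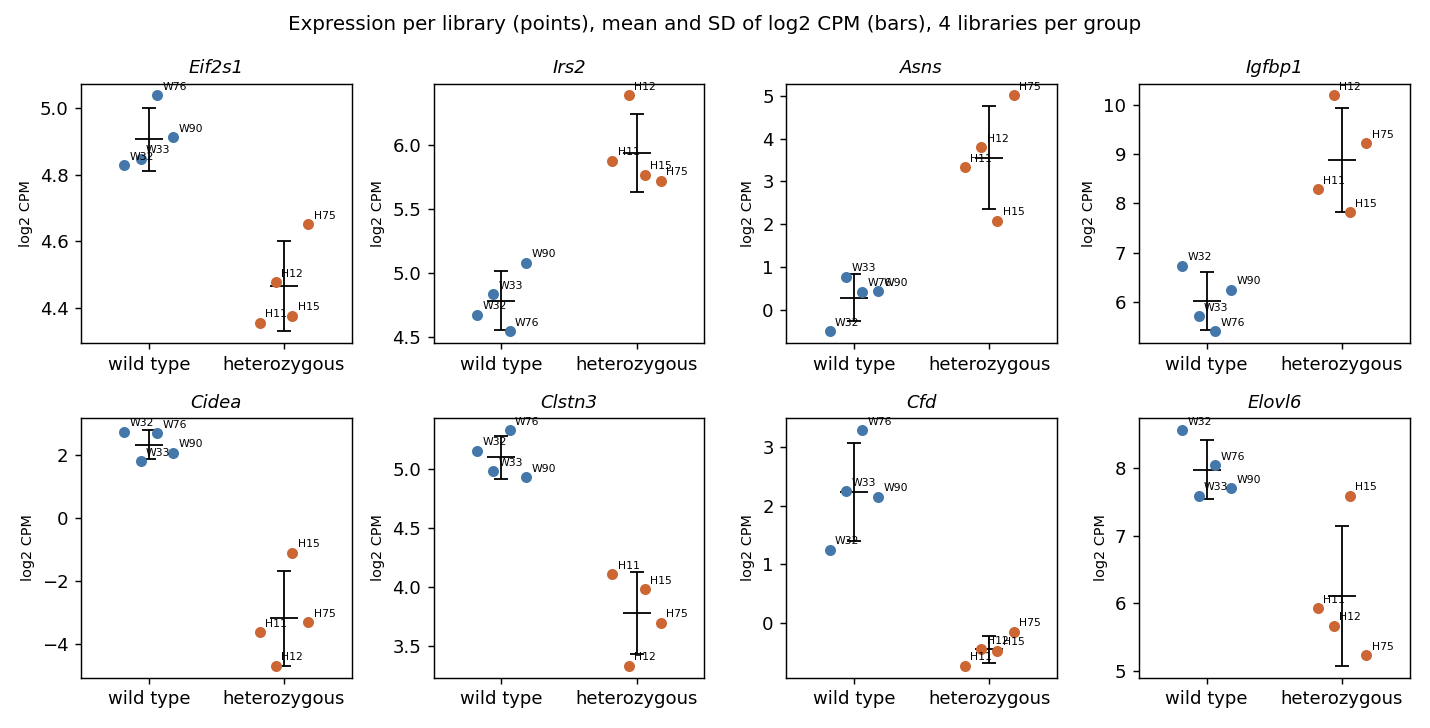
Each panel gives log2 CPM of 1 gene, with a point per library for 4 wild-type (blue) and 4 heterozygous (orange) livers and bars for the mean ± SD of log2 CPM. For Elovl6, an elongase of fatty acid synthesis, library H15 lies at 193 CPM within the wild-type range, and for the other genes drawn the groups do not overlap.

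On GRCm38, Cidea lies on chromosome 18 from 67343604 to 67367785, Clstn3 on chromosome 6 from 124430759 to 124464794 and Cfd on chromosome 10 from 79890853 to 79892655. Irs2 lies on chromosome 8 from 10984681 to 11008458, Asns on chromosome 6 from 7675169 to 7693254 and Igfbp1 on chromosome 11 from 7197782 to 7202546. These 6 genes are protein-coding. Exons of Irs2, Plk3, Mt2, Acaa1b, Slc25a10, Eif2a, Eif2ak1, Eif2ak2 and Eif2ak3 overlap an annotated transcript on the other strand, and whether counting used strand is not given in the sources used here, so part of their reads can come from the other strand. Exons of Snhg11 overlap Gm25187 on the same strand.

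Of 44 gene lists fixed beforehand and tested with camera at a preset correlation of 0.01, 22 passed an adjusted p of 0.05, 16 higher and 6 lower in heterozygous livers. With a correlation estimated from the data 0 lists passed, 4 had an unadjusted p under 0.05, and fry called 1. That list, the insulin, growth hormone and IGF axis, had 12 of 17 genes with a higher mean in heterozygous livers (fry adjusted p = 0.00233). Its camera adjusted p was 5.09e-06, with adjusted p = 0.0794 with an estimated correlation. Irs2, Socs2, Igfbp1, Igfbp4 and Igfbp2 passed as higher adjusted over the list alone, Igfbp2 being named after its values were seen. Igfbp4, another binding protein of insulin-like growth factors, averaged 824 ± 34.1 CPM in wild-type and 1146 ± 176 CPM in heterozygous livers (SD, n = 4 each). Over all genes edgeR called 0 of the 17, with 6 higher at an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 0.

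Targets of ATF4 and CHOP, transcription factors induced when eIF2α is phosphorylated, lay higher than other genes (camera adjusted p = 2.97e-05), with adjusted p = 0.372 with an estimated correlation. Of 31 tested targets, 23 had a higher mean, and Asns, Ppp1r15a, Chac1 and Mthfd2 passed adjusted over the list alone. Each of these 4 was higher in all 4 heterozygous libraries than in any wild-type library. Chac1, which degrades glutathione, averaged 1.40 ± 0.609 and 3.72 ± 1.34 CPM, and Mthfd2, a mitochondrial folate enzyme, 0.646 ± 0.228 and 1.68 ± 0.724 CPM (SD, n = 4 each). Over all genes edgeR called 0 targets, with 8 higher at an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 0. The list median relative to the wild-type mean was 0.10 in H11, 0.43 in H12, 0.12 in H15 and 0.27 in H75, against -0.092 to 0.14 in wild-type libraries. Genes of amino acid and urea metabolism, of cytosolic aminoacyl-tRNA synthetases and of ER chaperones also lay higher (camera adjusted p = 0.00842, 0.0114 and 6.31e-04). The 3 lists had adjusted p = 0.597, 0.714 and 0.714 with an estimated correlation. In H11, H12, H15 and H75 the median of the ER chaperones was -0.057, 0.62, -0.24 and 0.52, against -0.15 to 0.22 in wild-type libraries, and that of the synthetases -0.040, 0.28, 0.022 and 0.17, against -0.090 to 0.081. The median of amino acid and urea metabolism was 0.066, -0.0018, 0.0057 and 0.28, against -0.099 to 0.089. Slc38a2 alone passed adjusted over the list alone in the first of them (adjusted p = 0.0112, edgeR), and 0 genes did in the others, where 0 and 2 genes were higher at an unadjusted p under 0.05.

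Acute phase genes, which the liver transcribes in inflammation, had a higher mean in heterozygous livers for all 28 members, and library H15 stood apart from the other heterozygous libraries. The list median relative to the wild-type mean was 0.55 in H11, 0.98 in H12, 0.85 in H75 and 0.045 in H15 on the log2 scale, against -0.11 to 0.11 in wild-type libraries. The metallothioneins Mt1 and Mt2, which can share reads, had log2 fold changes of 4.76 and 5.58. Socs3, a feedback inhibitor of interleukin-6 signalling, averaged 2.81 ± 1.26 and 33.6 ± 25.7 CPM, and Saa1, a serum amyloid A gene, 22.4 ± 11.3 and 291 ± 271 CPM (SD, n = 4 each). In H15 Socs3 was at 3.95 CPM and Saa1 at 20.9 CPM, both inside the wild-type range. Adjusted over the list alone, 20 members passed as higher. Over all genes edgeR called 0, with 20 higher at an unadjusted p under 0.05, while DESeq2 called 10 and limma-voom 0. The camera adjusted p was 3.63e-22, with adjusted p = 0.400 with an estimated correlation. Without H15, the heterozygous library nearest to wild type in this list, edgeR called 16 members over all genes as higher.

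Immediate early genes, which respond to growth factors and cytokines within minutes, also lay higher (camera adjusted p = 1.10e-15), with adjusted p = 0.386 with an estimated correlation. Adjusted over the list alone, 16 of 20 tested members passed as higher, led by Egr1, Socs3, Junb and Gadd45g. The 1 member that passed as lower was Ccn1, named after its values were seen (log2 fold change -0.74). Junb averaged 13.3 ± 3.05 and 131 ± 105 CPM, and was at 15.9 CPM in H15, inside the wild-type range. The list median was 0.65 in H11, 2.35 in H12, 0.38 in H15 and 1.19 in H75. Over all genes edgeR called 0, with 16 higher and 1 lower at an unadjusted p under 0.05, while DESeq2 called 7 and limma-voom 0. Markers of neutrophils moved with these lists (camera adjusted p = 1.64e-05), with adjusted p = 0.438 with an estimated correlation. Lcn2, S100a9, Il1b and S100a8 passed as higher adjusted over the list of 6 alone. Lcn2 is also in the acute phase list, and S100a9 averaged 0.320 ± 0.136 and 1.41 ± 1.02 CPM (SD, n = 4 each). Markers of Kupffer cells and of sinusoidal endothelium lay higher by camera as well (adjusted p = 0.0155 and 0.0114), with adjusted p = 0.714 for both with an estimated correlation. Their medians per library overlapped between the groups (exact two-sided permutation p = 0.486 and 0.543). Without H15 the endothelial list no longer passed camera (adjusted p = 0.131).

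Genes of fatty acid and triglyceride synthesis had lower means in heterozygous livers for 23 of 26 members, with H15 again near the wild-type libraries. The list median was -0.94 in H11, -1.10 in H12, -1.28 in H75 and 0.15 in H15, against -0.13 to 0.13 in wild-type libraries. The elongase Elovl5 averaged 995 ± 183 CPM in wild-type and 477 ± 237 CPM in heterozygous livers (SD, n = 4 each), and Elovl6 261 ± 84.0 and 85.7 ± 72.3 CPM. Pklr, liver pyruvate kinase, averaged 469 ± 58.8 and 253 ± 108 CPM, and Gpam, which starts glycerolipid synthesis, 374 ± 73.9 and 225 ± 81.5 CPM. Scd1, a desaturase named after its values were seen, took 2.17 to 3.16% of counts in wild-type libraries, 0.591% in H11, 0.345% in H12, 0.352% in H75 and 2.47% in H15. The camera adjusted p of the list was 2.03e-13, with adjusted p = 0.438 with an estimated correlation. Over all genes and adjusted over the list alone edgeR called 0, with 11 lower at an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 0. Without H15, the heterozygous library at the wild-type level of this list, 16 members passed edgeR's test over all genes as lower, a count that leaving out such a library favours.

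Cholesterol synthesis genes lay lower as well (camera adjusted p = 2.30e-04), with adjusted p = 0.639 with an estimated correlation. In that list 19 of 25 members had a lower mean. Sc5d, a sterol desaturase, and Acat2, which makes acetoacetyl-CoA, were at 538 and 133 CPM in H15, inside the wild-type range, and at 296 to 334 and 70.7 to 75.6 CPM in the other heterozygous libraries. EdgeR called 0 members over all genes or adjusted over the list alone, with 8 lower at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. Genes of gluconeogenesis and glycogen did not pass camera (adjusted p = 0.240), and their median log2 fold change of -0.19 and mean of 0.03 differed in sign. Irs2 and Igfbp1 passed as higher and Ppp1r3c, a glycogen-targeting phosphatase subunit, as lower adjusted over that list alone. Ppp1r3c averaged 117 ± 20.1 and 74.8 ± 13.4 CPM (SD, n = 4 each). In xenobiotic metabolism, which did not pass camera (adjusted p = 0.134), the cytochrome gene Cyp3a13 passed as higher adjusted over the list alone (adjusted p = 0.0322, edgeR).

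**Figure D2:**
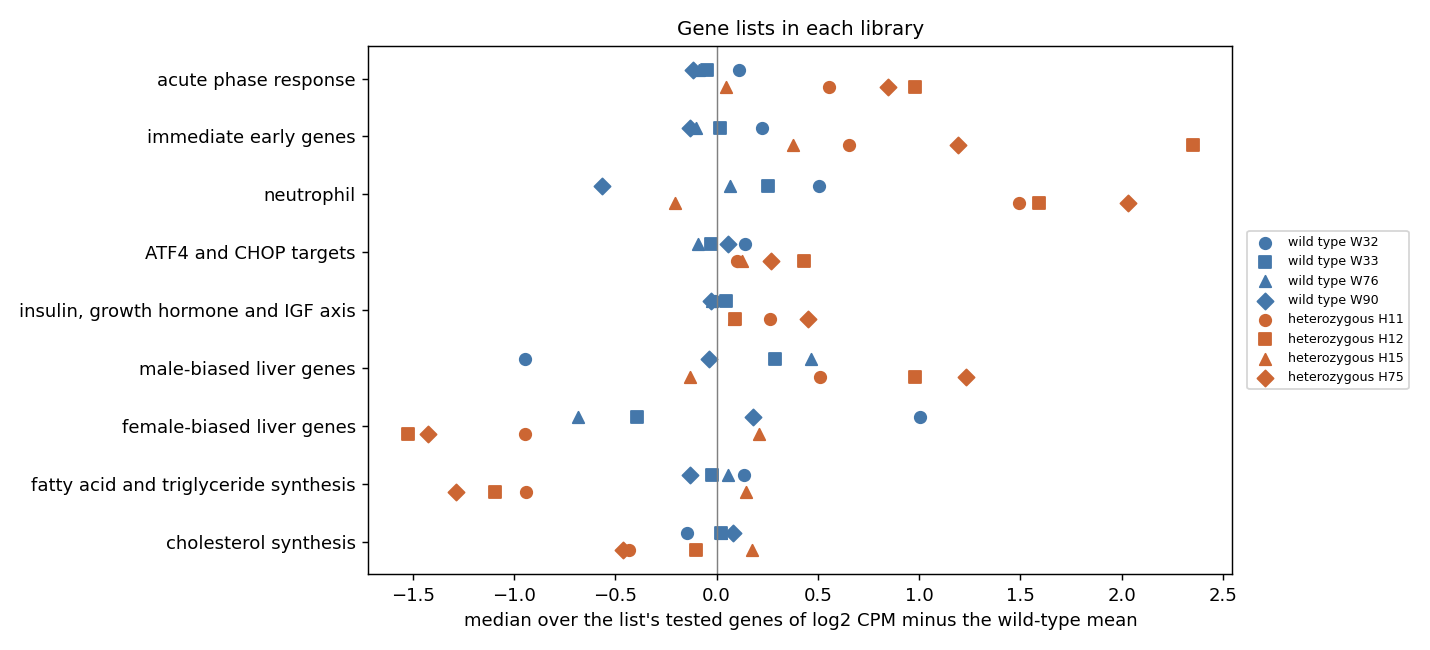
For each of 9 gene lists the horizontal axis gives the median over its tested genes of log2 CPM minus the wild-type mean, with a marker per library (wild type blue, heterozygous orange). In the acute phase list H11, H12 and H75 lie from 0.55 to 0.98 and H15 at 0.045, and in fatty acid and triglyceride synthesis they lie from -1.28 to -0.94 and H15 at 0.15.

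Sex-biased liver genes varied widely within both genotypes. Male-biased genes lay higher in heterozygous livers (median log2 fold change 0.56, camera adjusted p = 6.26e-08), with adjusted p = 0.572 with an estimated correlation. Female-biased genes lay lower (median -0.74, camera adjusted p = 0.00107), with adjusted p = 0.575 with an estimated correlation. Major urinary protein genes, a family of near-identical copies that can share reads, lay higher (median 0.77, camera adjusted p = 1.85e-08), with adjusted p = 0.572 with an estimated correlation. Over all genes and adjusted over each list alone edgeR called 0 members of the 3 lists, with 9 and 5 higher and 3 lower at an unadjusted p under 0.05 in the male-biased, urinary protein and female-biased lists. DESeq2 called 1 male-biased gene and 0 in the others, and limma-voom 0. The male-biased median was -0.95 in W32 and -0.13 in H15, and without W32 the median log2 fold change was 0.30. That of the female-biased list was -1.16 without H15. Its median per library was 1.005 in W32, -0.39 in W33, -0.69 in W76 and 0.18 in W90. In H11, H12, H15 and H75 it was -0.94, -1.53, 0.21 and -1.43, so W32 lay highest of all libraries. The urinary protein median was -0.91, 0.038, 0.92 and -0.16 in W32, W33, W76 and W90. It was 0.54, 1.38, -0.36 and 1.41 in H11, H12, H15 and H75, so W32 lay lowest. Selenbp2 averaged 186 ± 179 CPM in wild-type and 1302 ± 797 CPM in heterozygous livers (SD, n = 4 each). The Y-linked gene Ddx3y was at 35.2 to 57.0 CPM over the 8 libraries. Xist was at 0.151 to 0.424 CPM in wild-type and 0 to 0.120 CPM in heterozygous libraries. Its exact two-sided permutation p was 0.0286 (adjusted p = 0.210 over 22 measures).

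Cytosolic ribosomal protein genes had a higher mean for 62 of 64 members (median log2 fold change 0.25, camera adjusted p = 6.61e-15), with adjusted p = 0.597 with an estimated correlation. The list median was 0.067 in H11, 0.37 in H12, 0.15 in H15 and 0.44 in H75, against -0.18 to 0.27 in wild-type libraries. Rpl27a averaged 61.8 ± 9.60 and 86.7 ± 13.5 CPM (SD, n = 4 each). EdgeR called 0 of the 64 over all genes or adjusted over the list alone, with 14 higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Lists of oxidative phosphorylation, autophagy and lysosome, and secreted plasma proteins also lay higher (camera adjusted p = 0.00212, 0.00710 and 0.00921), with adjusted p = 0.770, 0.572 and 0.683 with an estimated correlation. NRF2 targets lay lower (camera adjusted p = 0.0147), with adjusted p = 0.572 with an estimated correlation. Ribosomal and small structural RNA, with 6 of 18 listed genes tested, lay lower (camera adjusted p = 0.0220), with adjusted p = 0.572 with an estimated correlation. Its median was -1.11, -1.09, 0.075 and -0.81 in H11, H12, H15 and H75, against -0.66 to 0.58 in wild-type libraries. Rn7s1 and Rn7s2, which can share reads, had the same log2 fold change in the authors' deposited table (-0.798). Differences in the depletion of ribosomal RNA between libraries were not tested. The lists of oxidative phosphorylation and of ribosomal and small structural RNA no longer passed camera once the gene length trend was removed, a setting chosen after seeing the data. Markers of adipocytes and mesothelium lay lower (camera adjusted p = 0.0123), with adjusted p = 0.438 with an estimated correlation. In this last list Cfd and Cidec, another lipid droplet protein, passed adjusted over the list alone, while Fabp4 had a log2 fold change of 0.0076.

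The libraries spread widely within the heterozygous group. The first principal component of log2 CPM held 37.6% of the variance, with scores of -23.7 to -11.3 in wild-type libraries, 3.40 in H11, 51.2 in H12, 45.6 in H75 and -25.7 in H15. Mitochondrially encoded transcripts took 6.36 to 7.34% of counts in wild-type and 5.26 to 6.32% in heterozygous libraries (n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.210 over 22 measures). The smallest adjusted p of the 22 measures was 0.210. Xist, higher in every wild-type than in any heterozygous library, also had an exact permutation p of 0.0286 (adjusted p = 0.210). The median level of adipocyte and mesothelium markers was -0.32 to -0.10 in heterozygous libraries and -0.065 to 0.10 in wild-type libraries (exact permutation p = 0.0286, adjusted p = 0.210). Medians of periportal, neutrophil, cholangiocyte, lymphocyte and erythroid markers had exact permutation p of 0.0571, 0.114, 0.886, 0.714 and 0.543. The 1 tested pancreatic acinar gene was at 0.96 to 1.06 in H11, H12 and H75 and at -0.018 in H15, against -0.55 to 0.42 in wild-type libraries (exact permutation p = 0.0857).

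**Figure D3:**
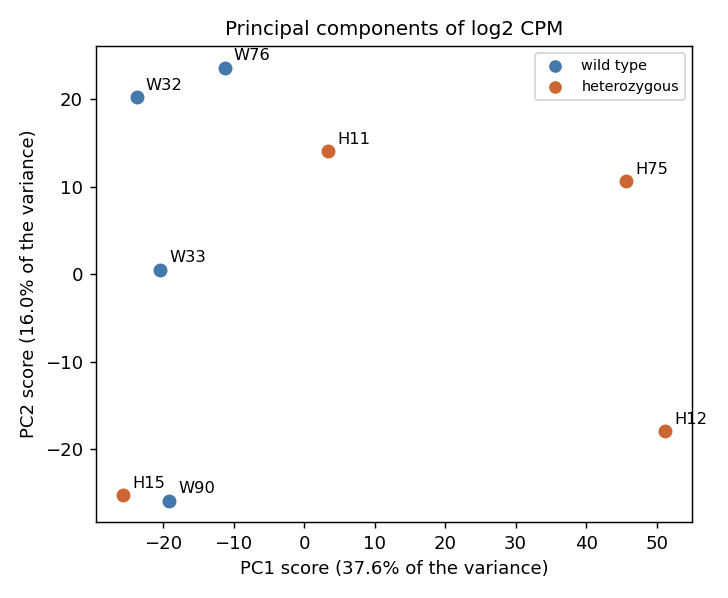
Scores of the 8 libraries on the first (37.6% of variance, horizontal) and second (16%, vertical) principal components of log2 CPM, with wild-type libraries in blue and heterozygous libraries in orange. H12 and H75 lie at 51.2 and 45.6 on the first component, and H15 at -25.7 lies beside the wild-type libraries.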

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

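All tests in this part were chosen after the result they measure was seen, except the median of lipid droplet genes, whose bounds were written first.

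Within a group of 4 libraries, 14 of 260 sets of values had a library far from the others by Dixon's criterion, where chance gives 13. Library H15 stood apart from the other heterozygous libraries in Eif2ak4 (10.2 CPM, others 6.01 to 6.15), Elovl5 (830 CPM, others 321 to 384), Elovl6 (193 CPM, others 37.7 to 60.9) and Sc5d (538 CPM, others 296 to 334). It also did in Acat2 (133 CPM, others 70.7 to 75.6), Cidea (0.467 CPM, others 0.0385 to 0.1001) and the median of the gluconeogenesis and glycogen list (-0.068, others -0.23 to -0.21). Library H12 stood apart in Egr1 (374 CPM, others 36.2 to 89.3), Cidec (6.97 CPM, others 2.29 to 3.05) and Krt8 (564 CPM, others 165 to 208). Among wild-type libraries, W32 did in Mt2 (5.93 CPM, others 1.78 to 2.43), W33 in Socs3 (4.68 CPM, others 1.97 to 2.42), and W90 in Gpam (263 CPM, others 400 to 421) and the erythroid list median (-0.32, others 0.057 to 0.11).

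Acute phase, immediate early and fatty acid synthesis genes lay apart from wild type in H11, H12 and H75, while H15 lay near the wild-type libraries in the acute phase and fatty acid synthesis lists. A wrong genotype label of H15 was argued against by Eif2s1, at 20.8 CPM in H15 and at least 28.4 CPM in wild-type libraries. Depth was argued against by the totals, since that of H15 and that of another heterozygous library differed by a ratio of 1.002. Neutrophil RNA as the origin of the acute phase difference was argued against by S100a8 and S100a9, which added 1.53 CPM, or 0.0138%, of the 11120 CPM that the list added. A difference between animals in inflammation, feeding or handling is not in the labels and stays open as untested, as does the genotype.

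Cidea and Cfd were lower in all 4 heterozygous libraries. A first test of adipose tissue attached to wild-type livers missed its bound of 2%, as Adipoq and Plin1 reached 0, 2.26, 0.394 and 0.847% of the Cfd level in W32, W33, W76 and W90. A later test was chosen with its values known. Fabp4, abundant in adipocytes, differed by -0.027 CPM (SE 0.260) between wild-type and heterozygous livers, at most 10.7% of the 4.61 CPM of Cfd. It argues against adipose tissue as the source of the Cfd difference only if adipocytes hold about as much Fabp4 as Cfd RNA. That was not measured here, so the test cannot decide. Retn, at 0.113 to 0.462 CPM in wild-type and 0 to 0.0402 CPM in heterozygous libraries, goes with traces of adipose tissue. Lower expression of lipid droplet genes was met by 9 tested genes with a median log2 fold change of -0.61, 7 of them negative, over a range of -1.20 to 0.69, G0s2 and Cd36 being lower by 84.0 and 48.7 CPM and Plin2 and Hilpda not lower. A reduced lipid droplet program and traces of adipose tissue both stay open as hypotheses, with the genotype and the animals' condition not separated.

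Male-biased and urinary protein genes lay higher and female-biased genes lower in heterozygous livers. Samples from female mice were argued against by Ddx3y, at 35.2 CPM or more in all 8 libraries. Ddx3y cannot exclude female RNA mixed into a male sample. For mixed samples the test also used Xist, which was at most 0.424 CPM and met the bound set against them. Xist was higher in every wild-type library (0.151 to 0.424 CPM) than in any heterozygous library (0 to 0.120 CPM), so traces were not excluded. Reads shared within the Mup and Serpina1 families were argued against as the only source. The 18 male-biased genes outside these families had a median of 0.39, with 15 higher. Read sharing between paralogs of other families was not tested. Whether library W32 alone gives the pattern cannot be told apart from a difference between genotypes, since without it the male-biased median was 0.30, between the bounds set for either. Differences in growth hormone secretion between animals were not tested.

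The 8 libraries can be split into 4 and 4 in 35 ways, the real grouping included, and chance could not be excluded for the genes at an unadjusted p under 0.05, the DESeq2 calls or the gene lists. For 1332 genes at an unadjusted p under 0.05, 8 of the 35 splits gave as many, the real one included, and the highest of the others 2086. For 152 DESeq2 calls it was 4 splits, the highest of the others 342, and for 22 gene lists 7 splits, the highest of the others 26. The real grouping gave 0 edgeR calls, a count that every split must reach, so splits say nothing about it, and the highest of the others gave 10. The split with 342 DESeq2 calls set W32, W33, W90 and H15 against the rest, and differs from the real grouping by an exchange of W76 and H15.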

How the results depend on the processing

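The settings with a robust fit, the newer quasi-likelihood method, unannotated loci removed, fits without H15 by DESeq2, limma-voom or an estimated correlation, a length trend removed and annotation terms on other calls were chosen after seeing the data, and the others before. No paired analysis was possible because the columns carry no replicate number, so the planned replicate block was not run.

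EdgeR called 0 genes, with 1332 at an unadjusted p under 0.05, and stayed at 0 with other scaling factors, the stricter filter, limma-voom, a fold of 1.2 and abundant genes removed. It called 18 genes (15 higher, 3 lower) with no filter, and 1 lower gene at an adjusted p under 0.1, with the robust fit, with the newer method and with unannotated loci removed. DESeq2 called 152 (91 higher, 61 lower). Leaving out each library in turn gave 0 to 252 calls, 0 to 123 higher and 0 to 129 lower, the highest without H15 and 2 without W32. Without H15 DESeq2 called 757 (388 higher, 369 lower) and limma-voom 197 (96 higher, 101 lower). Of the 252 genes, 98 were also DESeq2 calls on all 8 libraries. The cause was not tested.

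Eif2s1 passed with DESeq2 alone (-0.44, adjusted p = 0.0207), and over 18 settings its log2 fold change ran from -0.53 to -0.39 and its adjusted p from 0.0207 to 0.633. Signs turned for Eif2a with upper quartile factors (-0.0034), library totals (-0.078), without W32 (-0.013) and without H75 (-0.047), against 0.049 without H15, for Eif2s2 (-0.018) and Eif2s3x (-0.048) with library totals, and for Eif2ak3 without H12 (-0.094) and without H75 (-0.031), against 0.32 without H11. Of 486 other comparisons of named genes, 424 kept side and direction and 54 passed where they had not.

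Camera called 22 lists, 0 with an estimated correlation, 1 with fry, 1 with an estimated correlation without H15, and 19 to 23 with a library left out. Of 616 comparisons of lists, 502 stayed on the same side of the threshold, 89 no longer passed and 25 newly passed. Direction was compared only for lists that passed with all libraries, of which 0 reversed. Lists that had not passed could turn, as cholangiocyte markers did from a median log2 fold change of 0.21 to -0.27 without H15. Gene length had a Spearman correlation of -0.163 with log2 fold change across genes, which are not independent replicates, and removing its trend kept 20 of the 22 lists, lost oxidative phosphorylation and ribosomal RNA, and added glycolysis and PPARα targets, again 22. Annotation terms went from 0 to 31 on the DESeq2 calls and to 20 KEGG pathways with camera. The overlap with the authors' deposited table went from 0 to 138 with DESeq2. At this depth and number of libraries, edgeR recovered 18% of simulated changes of 1.5-fold, so changes of that size were mostly not detectable. The simulated genes varied independently and no simulated library stood apart from its group, so such shares can overstate the power in these data. Larger differences did not pass either, as Mt2, 47.7-fold higher, had an adjusted p of 0.218 with edgeR.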

Other observations

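The tests of annotation terms and of insulin-repressed genes in this part were chosen after the results were seen.

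Of the 91 genes that DESeq2 called higher, 50 with a KEGG annotation and 76 with a GO biological process annotation entered the tests. Terms of inflammation and of hormone response were enriched among them. The hypergeometric test treats genes as independent, which does not hold for genes that move together. Of 35 splits of the libraries, 4 gave as many DESeq2 calls, the real one included. TNF signaling had 10 genes against 0.873 by chance (adjusted p = 2.89e-06), IL-17 signaling 7 against 0.533 (adjusted p = 7.73e-05) and response to lipopolysaccharide 9 against 0.814 (adjusted p = 2.27e-04), by hypergeometric tests. Osteoclast differentiation had 9 against 1.02 (adjusted p = 7.73e-05) and cellular response to hormone stimulus 5 against 0.156 (adjusted p = 4.22e-04). Fos and Jun, named after their values were seen, were in all 5 terms. In all 21 GO terms and 10 KEGG pathways passed for the higher genes and 0 for the lower genes. Camera over 309 KEGG pathways called 20, led by Ribosome (adjusted p = 6.75e-11), and 0 passed with an estimated correlation (Ribosome and TNF signaling both adjusted p = 0.935 with an estimated correlation) or with fry.

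Other genes of lowest p in their lists also separated the genotypes, without passing edgeR's test over all genes. Fabp2, an intestinal-type fatty acid binding protein also expressed in liver, averaged 65.6 ± 15.2 CPM in wild-type and 39.6 ± 5.88 CPM in heterozygous livers (SD, n = 4 each). Xbp1, a transcription factor of the unfolded protein response, averaged 127 ± 16.1 and 195 ± 53.7 CPM, higher in all 4 heterozygous libraries. Per1, a clock gene, was higher in all 4 as well, with a log2 fold change of 0.58. Pfkfb3, a regulator of glycolysis, had a log2 fold change of 1.26. Cyp1a2, a pericentral cytochrome, averaged 413 ± 78.3 and 587 ± 78.4 CPM.

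Higher Igfbp1 and Irs2 with lower fatty acid synthesis genes led to the hypothesis that insulin signalling might be lower in heterozygous livers. Of 8 other genes that insulin represses, 5 had a positive log2 fold change and the median was 0.12, between the bounds of 0 and 0.3 set for either outcome, with a range of -0.63 to 0.68. G6pc and Pck1 had log2 fold changes of 0.68 and 0.57, and Ppargc1a of -0.63. The hypothesis was left undecided.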
